A study of Mus musculus with 20 samples.

How the data were processed

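Expression was measured with Affymetrix mouse gene arrays on total RNA of C2C12 cells, a mouse myoblast line that forms muscle fibres when it is allowed to differentiate and takes on osteoblast traits under bone morphogenetic proteins. Per the labels, cells were grown in medium with serum, plated in multiwell plates and given fresh medium with methanol, with recombinant BMP4 or with one of 3 compounds known here by their code names 942, 178 and 181. The time between treatment and RNA extraction is not given in the sources used here. The 20 arrays comprised 2 of untreated cells, 3 of methanol, 2 each of BMP4 at 10, 100 and 300 ng/ml, and 1 each of every compound at 6.25, 12.5 and 25 µM. The treatment protocol lists neither 12.5 µM nor 100 ng/ml, and these doses were taken from the sample titles. Methanol was taken as the vehicle of the compounds because the protocol names it beside them, and untreated cells were taken as the control of BMP4.

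The deposited values were log2 signals, 1 per probe set and array, and were used as they stood. Per the submitters' processing notes they were made in Partek 6.5 with RMA, which corrects background, normalizes quantiles and summarises probes. Per the labels' protocols, most RNA was labelled by the standard Affymetrix method and some by a method called Affyexpress, and 3 samples were labelled by both methods so that the batches could be corrected. Whether a correction was applied to the deposited values is not given in the sources used here. The Affyexpress label was given for 4 arrays, namely BMP4 300 ng/ml replicate 1 and all 3 arrays of compound 942. The sample titles carry running numbers, 10 to 17 and 18 to 29, and each of these 2 runs starts with an untreated well. Compound 942 lay in the first run and compounds 178 and 181 in the second, and within each compound the title number rose with dose.

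The table held 41345 probe sets, of which 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 16010 were unnamed in it. No gene was named from a probe set with several symbols. The 22180 genes with a symbol of their own were tested, and for the 1082 with more than 1 probe set the probe set with the highest mean stood for the gene. Among genes called for BMP4 there were 209 further probe sets, and 162 of them had the same sign as the one used. Symbols are those of the annotation and can be old. No coordinates are given because no genome build was named for the values. Array medians lay between 4.93 and 5.05, and no 2 arrays of a group held identical values beyond 0.0363% of probe sets. The number of arrays was small, and the labelling term widened the errors of compound 942 further (median SE 0.273, against 0.136 for compound 178 with as many arrays). The labels do not say that the arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

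All tests were made with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per treatment and dose and a term for the labelling method was fitted to all 20 arrays, which left 5 residual degrees of freedom (6 without the labelling term), and was moderated with a trend on the mean signal (median prior 6.73 degrees of freedom). The single array of each compound dose was assumed to vary like the groups with several arrays. The labelling term rested on the 2 arrays of BMP4 300 ng/ml alone, so with this term replicate 2 alone gave the mean at 300 ng/ml. Contrasts were the mean over the doses of BMP4 minus untreated, the mean over the doses of each compound minus methanol, methanol minus untreated, slopes on log2 dose, and differences between compounds, as means and at each matched dose. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and intervals are 95% intervals without adjustment for the number of genes. By chance 1109 of the 22180 genes would have an unadjusted p under 0.05. The counts were lower for 942 (333), 178 (547), 181 (816) and methanol (634). The errors may therefore be too wide for these comparisons, and a count of 0 called genes is no evidence that nothing changed. Genes raised and lowered by BMP4 were tested as sets in each compound with cameraPR, and 23 gene lists were tested with camera, both with a preset correlation between genes of 0.01 and adjustment over the tests of a comparison. Camera was also run with an estimated correlation, and no list passed with it in any comparison tested. The lists covered BMP and SMAD targets, osteoblast, chondrocyte, adipocyte, myogenic, contractile and extracellular matrix genes, targets of TGF-beta, Wnt, Notch and p53, cell cycle, cholesterol synthesis, hypoxia, the NRF2, unfolded protein, heat shock, aryl hydrocarbon receptor, interferon and inflammatory responses, and endothelial, epithelial and macrophage markers. They held 473 entries, of which 425 were measured. Median expression of all genes moved by less than 0.1 on the log2 scale under quantile normalization or median centring in every main comparison.

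The lists, the comparisons, the alternatives except those named as added later, and the rule for named genes were fixed before the data were examined. By that rule the text names, for BMP4 and each compound, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose treated arrays all lay on the same side of all control arrays; in every comparison Id1, Id2, Id3, Smad6, Smad7, Runx2, Sp7, Alpl, Myod1 and Myog; and for each list up to 4 members with the largest change, among called members where any were called. For the other comparisons it names the 3 largest rises and the 3 largest falls among called genes. Not every gene that the rule covers is printed. Runx2 had no probe set with a symbol of its own and is not analysed here.

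The procedure was tested on simulated data with 200 changed genes among 22180 in each of 5 draws. For a log2 change of 0.5 it recovered 25.4% of the changed genes for BMP4, 35.5% for compound 178, 33.7% for compound 181 and 0.896% for compound 942. For a change of 1 the shares were 98.5%, 97.9%, 97.9% and 24.2%, and for a change of 2 they were 100% for BMP4, 99.7% for compound 178, 100% for compound 181 and 97.0% for compound 942. Between 5.05% and 6.28% of the calls were false. The simulated noise was independent between genes and arrays and held no effect of run or labelling, so these shares may not hold for the real arrays. Alternatives left out the labelling term, added a term for the run of title numbers, gave the doses of a treatment a common mean, dropped the trend, left out genes with a mean under 4.98 (12673 genes stayed), averaged probe sets, normalized quantiles again, centred medians, changed the controls, used 1 dose alone, required a log2 change of at least 1, estimated the correlation between genes, or left out each array in turn.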

Results

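Expression was profiled in C2C12 mouse myoblasts that had been left untreated or given methanol, BMP4 at 10, 100 or 300 ng/ml, or compound 942, 178 or 181 at 6.25, 12.5 or 25 µM. The title of the series presents its compounds, called ventromorphins, as small molecules that activate BMP signalling, and its design text sets the effects of the 3 drugs beside that of BMP4. Each BMP4 dose had 2 arrays, methanol 3, untreated cells 2 and each compound dose 1. Values are deposited log2 signals with array medians from 4.93 to 5.05. Arrays of the same group correlated at r = 0.982 to 0.991 over all probe sets. Arrays of different groups reached 0.994, and no pair lay below 0.967, so these values do not set the groups apart. The first principal component held 51.6% of the variance and the second 8.49%.

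BMP4, a ligand of the BMP receptors, raised genes of bone and connective tissue and lowered muscle genes. The mean over the 3 doses was set against untreated cells (2 arrays). Of its 6 arrays, 300 ng/ml replicate 1 went wholly into the labelling term and did not inform that mean. Sp7, the osteoblast transcription factor osterix, rose by 3.97 on the log2 scale (SE 0.40, adjusted p = 7.40e-05). Alpl, the tissue non-specific alkaline phosphatase that marks osteoblasts, rose by 3.18 (SE 0.44, adjusted p = 6.72e-04). The largest rise was that of Sfrp2, a secreted modulator of Wnt signalling, at 4.74 (SE 0.29, adjusted p = 2.67e-06). It was followed by Fmod at 4.34, Prg4 (lubricin) at 4.02, Aspn at 3.68, Omd at 3.36 and Hpgd, a prostaglandin-degrading enzyme, at 3.20; Fmod, Aspn and Omd encode small leucine-rich proteoglycans of the matrix. The largest falls were those of Nefl, the light neurofilament chain (-4.43, SE 0.19, adjusted p = 1.78e-07), R3hdml (-4.11) and Ankrd2, a muscle ankyrin repeat protein (-3.73), and then of Myh3, the embryonic myosin heavy chain (-3.59), Tnnc1 (-3.43), Chrng (-3.42), Casq2 (-3.41) and Sprr1a (-3.34). Myog, which encodes the differentiation factor myogenin, fell by 2.88 (SE 0.28, adjusted p = 5.45e-05). Alpl stood at 1.98 and Myog at -1.76 without BMP4 300 ng/ml replicate 2, an omission that leaves only 10 and 100 ng/ml in the mean, and Sfrp2 at 2.74 when its probe sets were averaged. With a common mean for the doses of a treatment, which adds the differences between doses to the spread, Alpl (adjusted p = 0.0921) and Myog (adjusted p = 0.130) did not pass.

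Of 22180 genes, 932 rose and 1021 fell with BMP4 by limma, 220 and 302 of them by at least 1 on the log2 scale. All BMP4 arrays lay apart from both untreated arrays for 679 of the raised and 786 of the lowered genes. The total of 1953 depended on the 2 control arrays, being 915 without untreated replicate 1 and 1200 without untreated replicate 2. With untreated and methanol arrays together as the control it was 3137, and with a term for the run of title numbers 2988. Within the 2 runs the called genes had medians of 0.76 and 0.62 where raised and -0.79 and -0.67 where lowered, values that come from the arrays the calls were made on and so do not test the count.

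Among 19 BMP and SMAD targets, 7 rose and 2 fell, against 11 and 2 adjusted over the list alone, and the list was higher than other genes (median 0.66, adjusted p = 5.64e-06; adjusted p = 0.431 with an estimated correlation). Smad6, an inhibitory SMAD that feeds back on the pathway, rose by 2.24 (SE 0.34, adjusted p = 0.00118), and Smad9, a SMAD that transmits the BMP signal, by 1.31 (adjusted p = 0.00140). Dlx2 rose by 1.69 (adjusted p = 0.0126), Dlx5 by 1.30 (adjusted p = 0.0262) and Smad7 by 1.12 (adjusted p = 0.0339). The calls of these 3 genes were lost without untreated replicate 1 (adjusted p = 0.112, 0.0983 and 0.179), without untreated replicate 2 (0.0831, 0.192 and 0.164) and without BMP4 300 ng/ml replicate 2 (0.129, 0.326 and 0.285). In that last setting the changes were smaller, at 1.11, 0.69 and 0.67. Without BMP4 10 ng/ml replicate 1 the adjusted p was 0.0644 for Dlx5 and 0.0557 for Smad7, and without methanol replicate 2 it was 0.0514 for Smad7. With a common mean for the doses it was 0.0798 for Dlx2, 0.205 for Dlx5 and 0.175 for Smad7. The Id genes, direct targets that encode inhibitors of myogenic transcription factors, did not pass in the model with the labelling term alone: Id1 stood at 1.03 (SE 0.40, adjusted p = 0.162), Id2 at 0.60 (adjusted p = 0.261) and Id3 at 0.98 (adjusted p = 0.0590). Without BMP4 10 ng/ml replicate 2 they passed, at 1.36 (adjusted p = 0.00262), 0.82 (adjusted p = 0.0106) and 1.19 (adjusted p = 0.00452), and they also passed with both BMP4 10 ng/ml arrays left out (1.10, 0.76 and 1.18, adjusted p = 0.00954, 0.0174 and 0.00538). With a term for the run of title numbers, Id1 (1.13, adjusted p = 0.0452) and Id3 (1.06, adjusted p = 0.00933) passed. The signal of Id1 was 9.04 in BMP4 10 ng/ml replicate 1 and 7.04 in replicate 2, against 7.15 ± 0.19 (SD, n = 2) in untreated cells. Id3 also passed without BMP4 10 ng/ml replicate 1 (adjusted p = 0.0492) and without BMP4 100 ng/ml replicate 2 (adjusted p = 0.0133), and over all arrays with methanol as the control (1.04, adjusted p = 0.0192), with untreated and methanol arrays together as the control (adjusted p = 0.00794), without the labelling term (adjusted p = 0.0260) and with a common mean for the doses (adjusted p = 0.0471).

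**Figure D1:**
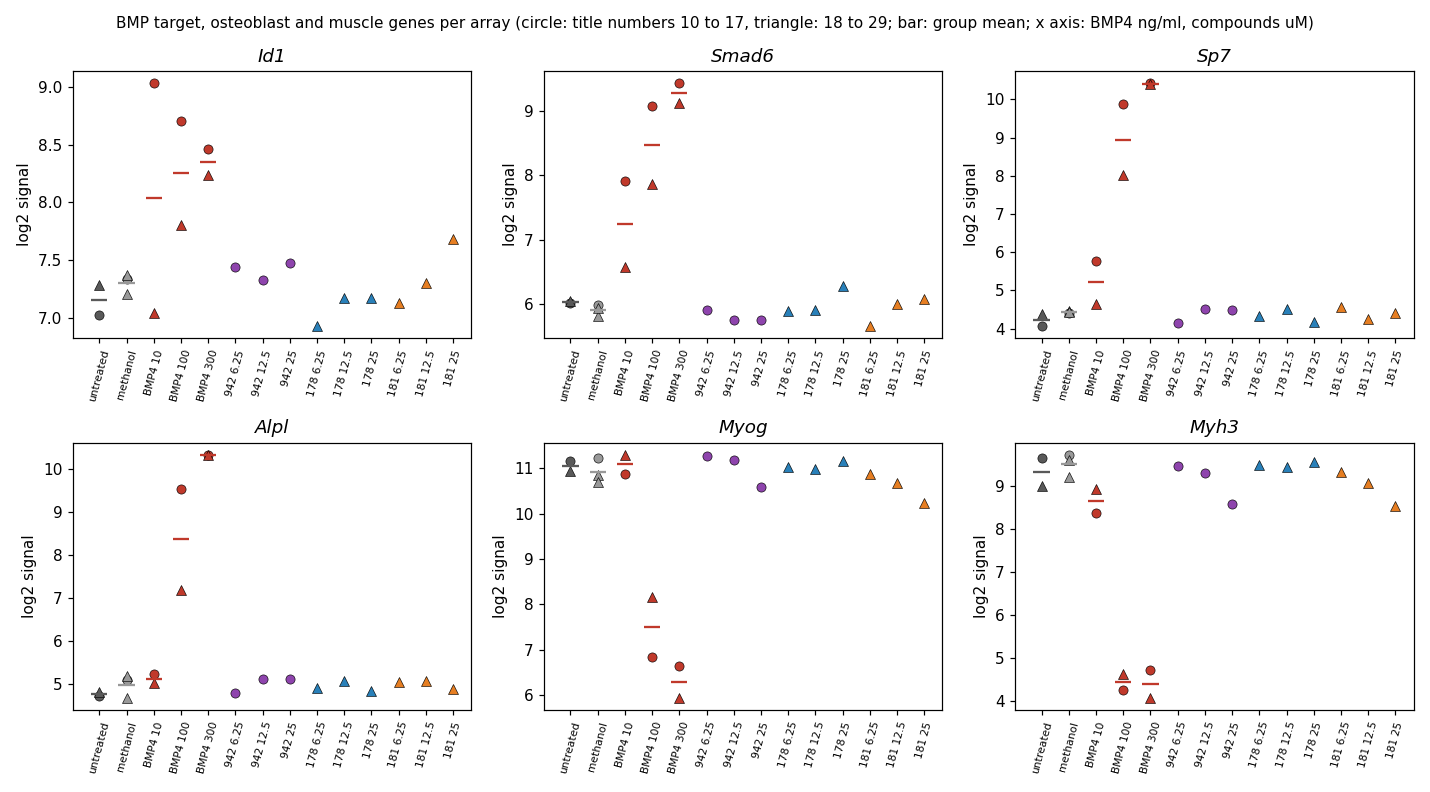
Log2 signal of 6 genes on every array, by treatment and dose (circles for title numbers 10 to 17, triangles for 18 to 29, bars for group means where a group has several arrays). Sp7 and Alpl reached group means of 10.41 and 10.33 at BMP4 300 ng/ml, while their signals in the compound arrays stayed between 4.15 and 5.13.

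The contractile list, 50 genes of the sarcomere and neuromuscular junction, held 43 genes that fell and 0 that rose with BMP4 by limma, with the same counts adjusted over the list alone (median -1.76, adjusted p = 2.99e-49; adjusted p = 0.103 with an estimated correlation). Of 18 myogenic regulators, 11 fell, and adjusted over the list alone 13 fell and 1 rose (median -0.66, adjusted p = 8.57e-11; adjusted p = 0.122 with an estimated correlation). Beside Myog, the calls included Rbm24 (-2.22), Heyl (-2.15) and Cdh15, the M-cadherin of myoblasts (-2.12). Myod1, the myoblast determination factor, fell by 0.67 (adjusted p = 0.0192). Its call was lost without untreated replicate 1 (adjusted p = 0.176), without untreated replicate 2 (0.0741) and without BMP4 300 ng/ml replicate 2 (-0.23, 0.546), and without that last array Rbm24 stood at -1.43 and Cdh15 at -1.36. With a common mean for the doses, Myod1 (adjusted p = 0.397), Rbm24 (0.172), Cdh15 (0.0771) and Heyl (0.0636) did not pass.

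Of 20 osteoblast genes, 13 rose and 1 fell, against 13 and 2 adjusted over the list alone (median 1.12, adjusted p = 3.63e-09; adjusted p = 0.281 with an estimated correlation). Phex, an endopeptidase of osteoblasts, rose by 1.51, a call lost without untreated replicate 1 (adjusted p = 0.0957). Of 31 extracellular matrix genes, 15 rose, and adjusted over the list alone 15 rose and 2 fell (median 0.32, adjusted p = 2.40e-10; adjusted p = 0.0634 with an estimated correlation), among them Col12a1 (2.17), Mfap5 (1.87) and Col6a2 (1.19). Of 19 genes of cholesterol synthesis and uptake, 8 rose and 1 fell, against 11 and 2 adjusted over the list alone (median 0.41, adjusted p = 1.58e-06; adjusted p = 0.402 with an estimated correlation), with Nsdhl at 0.66 and Sc5d at 0.65; Nsdhl stood at 0.43 with methanol as the control. Of 26 genes of the unfolded protein and integrated stress responses, 9 rose and 1 fell, against 13 and 2 adjusted over the list alone (median 0.30, adjusted p = 1.58e-06; adjusted p = 0.103 with an estimated correlation). Chac1, which degrades glutathione, rose by 1.23, Sesn2 by 0.71 and Asns, the asparagine synthetase, by 0.69.

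The cell cycle list (38 genes, median 0.15, adjusted p = 0.00660; adjusted p = 0.682 with an estimated correlation) and the hypoxia list (17 genes, median 0.12, adjusted p = 0.0361; adjusted p = 0.605 with an estimated correlation) also passed as higher. Methanol alone moved the cell cycle list nearly as far from the same untreated arrays (median 0.12, 32 of 38 higher, adjusted p = 0.00682), so its rise cannot be assigned to BMP4. With methanol as the control, Rrm2 stood at 0.24 instead of 0.44 and Ccnb2 at 0.20 instead of 0.38, and neither passed (adjusted p = 0.172 and 0.0941). In the cell cycle list, 2 genes rose and 1 fell, and in the hypoxia list 6 rose and 1 fell, with the same counts adjusted over each list alone. Egln3, an oxygen-sensing prolyl hydroxylase, went the other way from the hypoxia list and fell by 1.28 (SE 0.13, adjusted p = 7.72e-05). The other 14 lists did not pass. Within the TGF-beta list, 6 genes rose and 4 fell (7 and 5 adjusted over the list alone), including Postn (2.90), Ccn2 (1.47) and Ankrd1 (-1.81), and within the adipocyte list 4 rose and 2 fell, including Fabp4, a fatty acid carrier (3.12), and Pparg (1.06). The inflammatory list held 3 that rose and 4 that fell (3 and 5 adjusted over the list alone), with Ptgs2, the inducible cyclooxygenase, at 1.75 and Cxcl12 at 1.55, and the p53 list 3 and 4 (4 and 4), with Fas at 1.29 and Eda2r at -1.37. In the NRF2 list (adjusted p = 0.0897), 3 rose and 2 fell (7 and 3), and Slc7a11, the cystine transporter, was at 1.23 (0.70 with its probe sets averaged). Among chondrocyte genes 3 rose and 1 fell, among Wnt targets 2 and 1 (3 and 1), among Notch targets 1 and 2 (1 and 3), among heat shock genes 0 and 2 (Hspa4l, -1.05), among interferon genes 0 and 1, among epithelial markers 1 and 1 (Krt14, 3.12) and among aryl hydrocarbon receptor genes 1 and 0. Of the endothelial and macrophage markers 0 rose and 0 fell by limma. For the lists without a second pair of counts, the counts adjusted over the list alone were the same.

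The response to BMP4 grew with dose, and part of it was present at the lowest. At 10 ng/ml (2 arrays) Sfrp2 rose by 3.16, Fmod by 2.84 and Car3, a carbonic anhydrase, by 2.76, while Nefl fell by 3.61, R3hdml by 3.37 and Msln, mesothelin, by 2.53. At that dose Myog stood at 0.03 (adjusted p = 0.989), Sp7 at 0.99 (adjusted p = 0.519), Alpl at 0.37 (adjusted p = 0.879), Myod1 at 0.19, Rbm24 at 0.25 and Smad6 at 1.21 (adjusted p = 0.251). With the labelling term, the values at 300 ng/ml rest on replicate 2 alone. At that dose Sp7 had risen by 6.18, Alpl by 5.56, Smad6 by 3.09 and Smad7 by 2.03, and Myog had fallen by 5.12 and Myod1 by 1.54. Genes called by limma numbered 244 at 10 ng/ml, 2030 at 100 ng/ml and 1770 at 300 ng/ml. These counts moved with single arrays: at 10 ng/ml to 63 without untreated replicate 1, 100 without untreated replicate 2, 93 without BMP4 10 ng/ml replicate 1 and 146 without methanol replicate 2; at 100 ng/ml to 1116 without untreated replicate 1, 1266 without untreated replicate 2 and 1324 without BMP4 100 ng/ml replicate 1; and at 300 ng/ml to 1164 without untreated replicate 1. Without the labelling term 300 ng/ml had 2902 calls, so the order of the 2 higher doses is open. With a term for the run the counts were 595, 3082 and 2678, and without a trend 10 ng/ml had 140.

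Along the 3 doses, 514 genes rose and 683 fell per doubling of dose, with 300 ng/ml given by replicate 2 alone. The largest slopes belonged to Panx3, a channel protein of cartilage and bone (1.21, adjusted p = 6.50e-06), Sp7 (1.07) and Alpl (1.05) among rises, and to Myog (-1.05), Myh3 (-0.98) and Actc1 (-0.95), a sarcomeric actin, among falls. Of the fixed lists 5 were higher and 5 lower with dose. The cell cycle list, although higher than in untreated cells at 10 ng/ml (median 0.27, adjusted p = 1.02e-12; adjusted p = 0.533 with an estimated correlation), was lower with rising dose (median slope -0.08, adjusted p = 5.42e-12; adjusted p = 0.275 with an estimated correlation). The count of 1197 genes with a slope was 623 without BMP4 10 ng/ml replicate 2, 655 without BMP4 300 ng/ml replicate 2 and 1950 without the labelling term.

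In none of the 3 compounds did the osteoblast and muscle genes that answered BMP4 most pass the test. Sp7 stood at -0.07 in compound 942, -0.09 in 178 and -0.02 in 181 (means over 3 doses against methanol), and Alpl at 0.03, -0.04 and 0.02. Id1 stood at -0.11 [95% interval -1.79, 1.57] in 942, -0.21 [-1.05, 0.63] in 178 and 0.07 [-0.77, 0.91] in 181. Smad6 stood at -0.42, 0.12 and 0.00, and Myog at -0.60, 0.13 and -0.32. In the same order, Id2 stood at -0.08, 0.02 and 0.10, and Id3 at -0.24, -0.08 and 0.28. Smad7 stood at -0.03, -0.11 and -0.10, and Myod1 at -0.06, -0.11 and -0.16. Some genes with the largest BMP4 changes stood on the BMP4 side in 181 without passing over all genes (adjusted p = 0.9998 each). Sfrp2 stood at 1.04 [0.43, 1.65] (1.08 within the run), Hpgd at 0.76 and Omd at 0.58. R3hdml stood at -1.13 [-1.81, -0.44] (-0.78 within the run), Sprr1a at -0.83, Ankrd2 at -0.73 and Casq2 at -0.63 (-0.37 without the 25 µM array). Others stood on the opposite side or near 0, with Fmod at -0.24, Prg4 at -0.016 and Nefl at -0.080. In 942, against the 1 methanol array of its run, R3hdml stood at -1.06 (-0.24 in the model), Ankrd2 at -0.76 (-0.25) and Casq2 at -0.63 (-0.091). Against that same array, Fmod (-0.68), Aspn (-0.52), Sfrp2 (-0.15) and Nefl (0.072) stood on the side opposite to BMP4. Of the raised genes, Hpgd (0.32), Prg4 (0.20) and Omd (0.048) stood on the BMP4 side there. The BMP and SMAD target list did not pass in compound 942 (median -0.12, adjusted p = 0.527), 178 (-0.02, adjusted p = 0.668) or 181 (0.01, adjusted p = 0.834), with 0 members called adjusted over the list alone in each. At 25 µM its medians were -0.16 (adjusted p = 0.496), 0.02 (adjusted p = 0.916) and 0.09 (adjusted p = 0.442). The osteoblast list did not pass either, with adjusted p = 0.264 in 942, 0.526 in 178 and 0.402 in 181.

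Set against the genes called for BMP4, whose medians were 0.69 for raised and -0.72 for lowered genes, the compounds moved by small amounts. The 1021 genes lowered by BMP4 had a median of -0.11 in compound 181 (adjusted p = 2.16e-18, 19.2% of them higher than in methanol), -0.04 in 942 (adjusted p = 0.0223) and -0.03 in 178 (adjusted p = 0.0197). The 932 genes raised by BMP4 had a median of 0.03 in 181 (adjusted p = 3.35e-04), -0.02 in 942 (adjusted p = 0.542) and 0.01 in 178 (adjusted p = 0.586). These adjusted p come from cameraPR with the preset correlation between genes. The 2 sets were not tested with an estimated correlation, under which no fixed list passed. At 25 µM the lowered genes had a median of -0.18 in 181 (adjusted p = 1.15e-18), -0.11 in 942 (adjusted p = 1.08e-07) and -0.02 in 178 (adjusted p = 0.0507), and the raised genes 0.08 (adjusted p = 5.17e-08), -0.02 (adjusted p = 0.997) and 0.05 (adjusted p = 0.00165). The compound's interval excluded the change that BMP4 made for 1890 of the 1953 genes in 181, 1934 in 178 and 1305 in 942, the compound with the widest errors. These genes were chosen for their BMP4 change, and its error is not counted, so high counts were favoured in advance. The contrast of BMP4 minus compound, which counts both errors, called 634 genes for 181, 781 for 178 and 173 for 942. Of these, 624, 775 and 172 were among the genes called for BMP4, in part because the contrast holds the BMP4 change itself. Leaving out 1 array gave 197 to 933 for 181, with 197 without untreated replicate 1, 303 without untreated replicate 2, 289 without methanol replicate 2, 327 without methanol replicate 3 and 238 without BMP4 300 ng/ml replicate 2. For 178 it gave 286 to 1060, with 286, 425, 422, 433 and 379 without the same arrays. For 942 it gave 53 to 483, with 53 and 82 without untreated replicates 1 and 2, 105, 57 and 68 without methanol replicates 1, 2 and 3, 107 without the 6.25 µM array of 942, 298 without BMP4 10 ng/ml replicate 2, and 309 and 483 without BMP4 100 ng/ml replicates 1 and 2. Without the labelling term 942 had 927, with a term for the run the counts were 1140 for 181, 1329 for 178 and 513 for 942, and with a common mean for the doses 140, 242 and 471. Without a trend they were 388 for 181 and 70 for 942.

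The single arrays of the compounds decided part of these medians. The raised genes in 181 had a median of 0.01 and did not pass without the 25 µM array of 181, and did not pass without methanol replicate 1 (0.0192). The lowered genes in 942 had a median of -0.00333 and did not pass without its 25 µM array, and did not pass without its 12.5 µM array (-0.0298), without methanol replicate 2 (-0.0365) or without BMP4 100 ng/ml replicate 1 or replicate 2. In a fit without the labelling term their median was -0.08 (adjusted p = 1.22e-07). The lowered genes in 178 did not pass without methanol replicate 1 (-0.0123), without methanol replicate 2 (-0.0228) or without the 6.25 µM array of 178 (-0.0228).

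**Figure D2:**
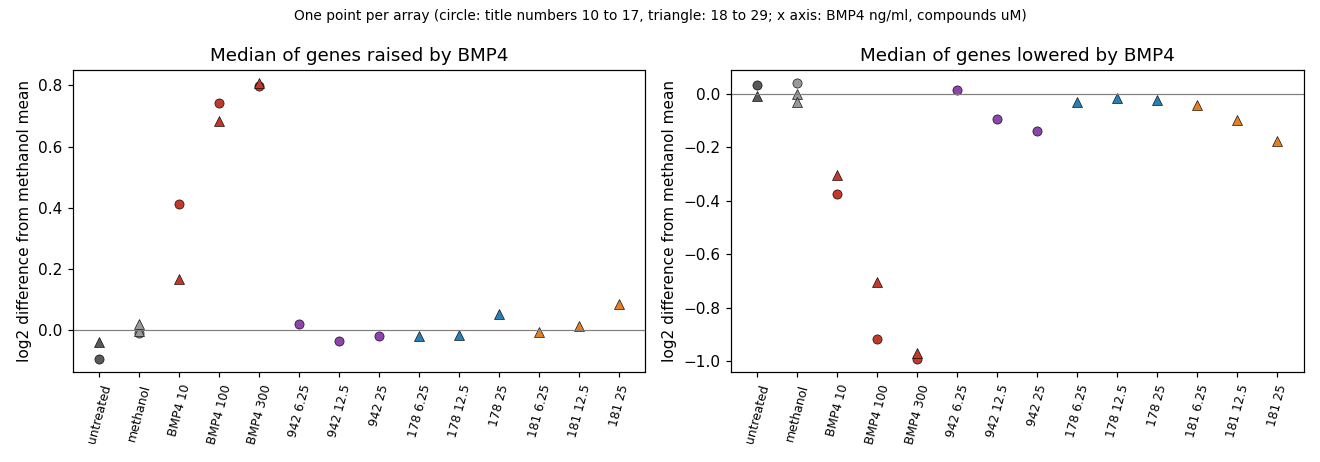
Median log2 difference from the methanol mean of the 932 genes raised (left) and the 1021 genes lowered (right) by BMP4, with 1 point per array (circles for title numbers 10 to 17, triangles for 18 to 29). The BMP4 300 ng/ml arrays stand at 0.80 and 0.81 on the left, and the 181 25 µM array at 0.08.

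Across genes, which are not independent replicates, the changes in compound 181 correlated with those of BMP4 at r = 0.236 and those in 178 at r = 0.0552, against highest values of 0.0214 and 0.0193 in 100 simulations without effects. Their covariances were 0.0128 and 0.00270, against simulated values near 0, and no control array was shared. The simulated noise was independent between genes, and leaving out 1 array moved the r of 178 between -0.0160 and 0.103. The simulated ranges are thus too narrow to judge r by. The value of 178 fell inside the simulated range without methanol replicate 1 (-0.0160) or the 25 µM array of 178 (0.0128), and was -0.0242 at the lowest dose. That of 181 was 0.128 without its 25 µM array and 0.0433 at the lowest dose. For 942 the labelling term shares the BMP4 300 ng/ml arrays with BMP4. Its r of 0.109 lay below the simulated mean of 0.240, and its covariance of 0.00978 stood beside a simulated 0.0105. With a common mean for the doses that r was -0.384, at the highest dose 0.265 and at the lowest 0.00891. With methanol as the control of BMP4 too, r was 0.355 for 181, 0.194 for 178 and 0.191 for 942. A shared control raises r without any effect, and no simulated value was computed for it.

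Compound 181 raised Slc7a11, the cystine transporter that feeds glutathione synthesis, by 1.68 on the log2 scale against methanol [95% interval 1.27, 2.10] (adjusted p = 0.0317), the single call of that comparison by limma. Its signal was 5.12, 6.11 and 7.19 at 6.25, 12.5 and 25 µM, each above the methanol arrays (4.45 ± 0.26, SD, n = 3). Slc7a11 was also among the genes raised by BMP4. With 1 called gene, the 0.0420 genes of overlap that would arise by chance are the share of all genes that BMP4 raised. An overlap of 1 gene therefore cannot show an excess. The call rested on few arrays. It was lost without methanol replicate 1 (1.54, adjusted p = 0.182), methanol replicate 2 (1.74, 0.159) or methanol replicate 3 (1.78, 0.0813). The same held without BMP4 10 ng/ml replicate 1 (1.68, 0.0695), BMP4 10 ng/ml replicate 2 (1.68, 0.0690) or the 12.5 µM array of 181 (1.70, 0.0903). In these settings the change itself stayed near its size, while without the 25 µM array of 181 it shrank (1.16, adjusted p = 0.9998). The call of Slc7a11 depended on single arrays in each case. The call was also lost when probe sets were averaged (0.996, adjusted p = 0.137), when the doses of a treatment had a common mean (adjusted p = 0.450), after further quantile normalization (0.0942), without dim genes (0.0559) and without a trend (0.0583). Within the second run alone the difference was 1.54.

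At 25 µM compound 181 had 4 called genes, all higher, namely Slc7a11 (2.74, adjusted p = 0.00732), the chemokine Ccl5 (1.49, adjusted p = 0.0351), Olfr1275 (1.36, adjusted p = 0.0351) and Ptn, the growth factor pleiotrophin (1.06, adjusted p = 0.0351); Ptn fell outside the rule for named genes and was chosen after its values were seen. Leaving out 1 array changed that count, to 1 without untreated replicate 1, untreated replicate 2, methanol replicate 2 or methanol replicate 3, to 2 without methanol replicate 1, and to 12 (11 higher, 1 lower) without either BMP4 10 ng/ml array. With a term for the run it was 25 (18 higher, 7 lower), with the BMP4 arrays left out 17 (13 higher, 4 lower), without a trend 2 and after further quantile normalization 1. The other 2 doses of 181 had 0 calls by limma, with 330 and 478 genes at an unadjusted p under 0.05, against 1416 at 25 µM and 816 for the mean over doses. Its slope on dose called 0 genes (787 unadjusted), with Slc7a11 at 1.04 per doubling (adjusted p = 0.897).

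Gene lists moved in compound 181 by less than single genes could show. The contractile list was lower, with 50 of 50 members below methanol, a median of -0.37 and 4 members called adjusted over the list alone, although 0 were called over all genes (adjusted p = 1.12e-26; adjusted p = 0.175 with an estimated correlation). Casq1, a calcium-binding protein of the sarcoplasmic reticulum, stood at -0.92 (adjusted p = 0.715) and Mb, myoglobin, at -0.91. Hypoxia and glycolysis genes were lower (median -0.21, adjusted p = 7.24e-09; adjusted p = 0.175 with an estimated correlation), with Egln3 at -0.59 (-0.35 without the 25 µM array), as were TGF-beta targets (median -0.13, adjusted p = 8.23e-07; adjusted p = 0.165 with an estimated correlation), with Cnn1 at -0.88 and Fst at -0.57, and myogenic regulators (median -0.14, adjusted p = 0.00896; adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone, these 3 lists had 4, 3 and 0 members called, all lower. The NRF2 list was higher (median 0.09, adjusted p = 2.53e-07; adjusted p = 0.165 with an estimated correlation), with 3 members called adjusted over the list alone against 1 over all genes, and Nqo1, a quinone reductase, at 0.64. Inflammatory genes (median 0.14, adjusted p = 0.0157; adjusted p = 0.165 with an estimated correlation) and aryl hydrocarbon receptor genes (median 0.11, adjusted p = 0.00887; adjusted p = 0.165 with an estimated correlation) were higher too, with 3 up and 1 down and with 2 up adjusted over the list alone, among them Cxcl5 (0.98) and Aldh3a1 (0.66). Cxcl5 stood at 0.52 without the 25 µM array and at 1.396 without that of 6.25 µM. In the aryl hydrocarbon receptor list Cyp1b1 stood at 0.50 and Cyp1a1 at 0.19. Nqo1 belongs to this list as well as to the NRF2 list, so the 2 lists overlap. At 25 µM the aryl hydrocarbon receptor list was not higher as a whole (median -0.055, 5 of 9 members lower, adjusted p = 0.282). The other 16 lists did not pass.

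**Figure D3:**
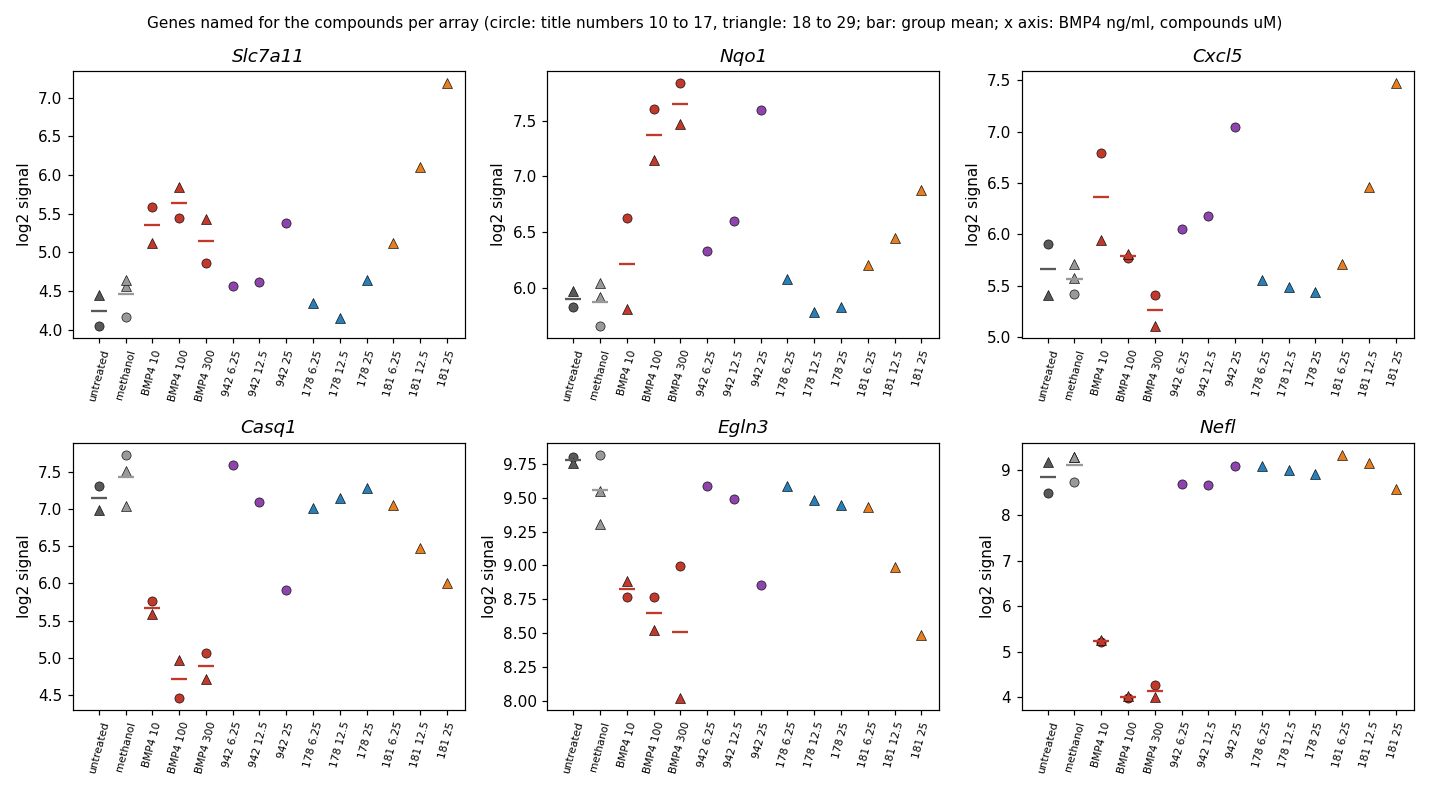
Log2 signal of 6 genes on every array, by treatment and dose (circles for title numbers 10 to 17, triangles for 18 to 29, bars for group means where a group has several arrays). Slc7a11 stood at 5.12, 6.11 and 7.19 in the arrays of compound 181 and between 4.15 and 4.64 in those of compound 178.

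Compound 942 called 0 genes by limma against methanol, with 333 at an unadjusted p under 0.05 and a lowest adjusted p of 0.164. Its 95% interval lay within a 2-fold change either way for 82.2% of genes. The cell cycle list was lower (36 of 38 members, median -0.22, adjusted p = 1.14e-06; adjusted p = 0.861 with an estimated correlation). For the members compared within the run of 942, that fall was small or absent. Against the methanol array of its own run, Mcm5 stood at -0.10 (-0.41 in the model), Kif20a at -0.054 (-0.40), Ccnb2 at -0.11 (-0.38), Cenpa, a centromeric histone, at 0.12 (-0.41) and Rrm2 at 0.16 (-0.22). Without the labelling term Cenpa stood at 0.14. Hypoxia and glycolysis genes were lower (15 of 17, median -0.25, adjusted p = 2.67e-06; adjusted p = 0.861 with an estimated correlation), with Egln3 at -1.22 the 1 member called adjusted over the list alone, as were contractile genes (33 of 50, median -0.18, adjusted p = 0.00219; adjusted p = 0.861 with an estimated correlation), with Mb at -1.30 and Myh3 at -1.04 and 0 members called adjusted over the list alone. The other 20 lists did not pass. Measured from the methanol array of its own run, Egln3 stood at -0.51, Mb at -0.98 and Myh3 at -0.61, and of the hypoxia genes Ldha at -0.085 (-0.49 in the model) and Bnip3 at -0.49 (-0.74). A fit without the labelling term had 7 lists past the threshold. The term is the difference between the 2 arrays of BMP4 300 ng/ml, of which the 942 arrays held a share by covariance of -0.0284. The values of 942 in the model therefore carry a difference that its arrays did not share by this measure, and are uncertain by more than their SE.

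Along the doses of 942, a contrast between arrays of 1 labelling method, 0 genes were called (467 unadjusted), while 3 lists were higher and 7 lower. TGF-beta targets had a median slope of -0.15 per doubling with 18 of 19 members lower (adjusted p = 1.09e-14; adjusted p = 0.103 with an estimated correlation) and 6 members lower adjusted over the list alone. Contractile genes had a median slope of -0.31 with 49 of 50 lower (adjusted p = 4.08e-28; adjusted p = 0.256 with an estimated correlation) and 1 member lower adjusted over the list alone, and the NRF2 list a median slope of 0.04 (adjusted p = 7.57e-04; adjusted p = 0.256 with an estimated correlation) with 2 members higher adjusted over the list alone. Markers of another cell type moved along these doses too, as the endothelial list was higher in 8 of 8 members (median slope 0.13, adjusted p = 0.00493; adjusted p = 0.256 with an estimated correlation). Nqo1 stood at 0.63 per doubling and Casq1 at -0.84 in that compound.

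Compound 178 called 0 genes by limma (547 at an unadjusted p under 0.05), 0 along its doses (359 unadjusted) and 0 of the 23 lists, with a lowest adjusted p of 0.896 with an estimated correlation. Its 95% interval lay within a 2-fold change for 99.7% of genes, against 99.4% in compound 181. The contractile list did not pass, and Casq1 stood at -0.28 and Mybpc1 at -0.34. Slc7a11 was at -0.08 and Nqo1 at 0.02. With a term for the run of title numbers 3 lists passed, and 1 list passed without methanol replicate 1, without replicate 2 or without replicate 3.

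At matched doses the compounds were compared with each other directly, and 1 gene differed in the means over doses. Slc7a11 was lower in 178 than in 181 by a difference of -1.76 [95% interval -2.17, -1.35] (adjusted p = 0.0200). That call was lost without the 6.25 or 12.5 µM array of 178, without the 12.5 or 25 µM array of 181, with a common mean per treatment and after further quantile normalization. At 6.25, 12.5 and 25 µM the difference in Slc7a11 was -0.77, -1.96 and -2.55 (adjusted p = 0.110 at 25 µM, interval -3.26, -1.84). At each dose 178 and 181 had 0 called genes by limma, with 395, 548 and 1233 at an unadjusted p under 0.05. Their difference in Cxcl5 was -1.05 [-1.49, -0.61] and in Id1 -0.28 [-1.12, 0.56] over doses, and 99.3% of all genes had an interval within a 2-fold difference.

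Compound 942 differed from 178 and from 181 in 0 genes by limma over doses (401 and 364 unadjusted), and in 0 at 6.25, 12.5 and 25 µM (393, 352 and 423 against 178, and 349, 279 and 436 against 181). Its interval lay within a 2-fold difference for 81.5% of genes against 178 and for 81.9% against 181, and at 25 µM for 59.8% and 58.8%. In Slc7a11 it stood 1.04 [0.22, 1.87] above 178 and at -0.72 [-1.54, 0.11] against 181, and in Egln3 at -1.17 [-1.71, -0.63] against 178 and -0.63 [-1.17, -0.09] against 181. For Id1 the differences were 0.10 [-1.57, 1.78] and -0.17 [-1.85, 1.505], wide enough to hold a change of the size that BMP4 made. Without BMP4 100 ng/ml replicate 1 or replicate 2, 1 gene differed between 942 and 178, and without the latter 1 differed between 942 and 181.

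Methanol itself called 0 genes against untreated cells (634 unadjusted), and the cell cycle list was its single list past the threshold, as higher (32 of 38 members, median 0.12, adjusted p = 0.00682; adjusted p = 0.965 with an estimated correlation), with 0 members called adjusted over the list alone. Id1 stood at 0.15, Smad6 at -0.12, Sp7 at 0.21, Alpl at 0.22 and Myog at -0.13 in methanol against untreated cells.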

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

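No test in this part was chosen after its result was seen. The rule for values that differ between groups picked out 1 item, the difference in Slc7a11 between compounds 178 and 181. Slc7a11, the cystine transporter of the NRF2 list, had a mean signal over doses that differed by -1.76 on the log2 scale (178 minus 181, SE 0.19, adjusted p = 0.0200 by limma). Compound 178 itself stood at -0.08 against methanol and compound 181 at 1.68, so the difference came from the arrays of 181, and it was larger at each higher dose (-0.77, -1.96 and -2.55).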

How the results depend on the processing

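The settings below were fixed before the data were examined, except the 4 that left out the BMP4 arrays, the arrays of the highest compound dose or both BMP4 10 ng/ml arrays, which were chosen after the results had been seen. The cause of a change was not tested unless one is named. The main fit was not paired because replicate numbers follow the order of the accessions and the labels name no pairs. The runs of title numbers were used instead, as a term in an alternative fit and for differences within each run. Few arrays, and for 942 also the labelling term (median SE 0.273 against 0.136 for 178), limited precision, and lone arrays of a dose were assumed to vary like the other groups.

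Leaving out each array in turn gave 915 to 2252 genes changed by BMP4, 0 to 1 changed by compound 181, 623 to 1550 with a BMP4 dose trend, 0 to 1 that differed between 178 and 181, 0 to 1 between 942 and 178, and 0 to 1 between 942 and 181. It gave 2 to 4 lists past the threshold for 942 and 0 to 1 for 178. The median of BMP4-lowered genes ran from -0.0902 to -0.00333 in 942 and from -0.0401 to -0.0123 in 178, and that of BMP4-raised genes from 0.00635 to 0.0491 in 181. Without either BMP4 300 ng/ml array, compound 942 has no value against methanol, because it then cannot be told from the labelling method.

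A log2 change of at least 1 left 522 genes for BMP4 and 4 for its dose trend. With an estimated correlation 0 lists passed for BMP4, 0 for 942 and 0 for 181. Without the labelling term, 1950 genes had a BMP4 dose trend, 1 differed between 942 and 178, 2 differed between them at 25 µM, 7 lists passed for 942, and Cenpa stood at 0.14 in 942. With a term for the run of title numbers, 2988 genes changed with BMP4, 2211 had a dose trend, 1 differed between 942 and 178, and 3 lists passed for 178.

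With a common mean for the doses of a treatment, 0 genes changed with 181 and 0 differed between 178 and 181, while 10 lists passed for 942 and 4 for 181. The labelling term of that fit compares BMP4 300 ng/ml replicate 1 with all BMP4 doses and so takes up part of the dose effect. In 942, Myog then stood at 2.09, Chrng at 1.31, the BMP4-raised genes at a median of -0.264 and the BMP4-lowered genes at 0.241, and in 178 the lowered genes stayed at -0.0273 without passing.

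Compound 181 had 0 changed genes without a trend, without dim genes, with probe sets averaged and after quantile normalization. Without dim genes, the BMP4-lowered genes stood at -0.0322 in 942 and -0.0268 in 178, and neither passed. After quantile normalization they stood at -0.0452 in 942 without passing, and 0 genes differed between 178 and 181. After median centring 1 gene differed between 942 and 178. With untreated and methanol arrays together as the control, 3137 genes changed with BMP4, and the BMP4-raised genes stood at 0.0218 in 942 and 0.0332 in 178.

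At the highest dose alone, 4 genes changed with 181, 7 lists passed for 942, and in 178 the BMP4-raised genes stood at 0.0541 and the lowered genes at -0.0244. At the lowest dose alone, 244 genes and 5 lists passed for BMP4, 0 genes and 2 lists for 181, Myod1 stood at 0.19 and Rbm24 at 0.25 in BMP4, the BMP4-lowered genes at 0.0459 in 942 and -0.0319 in 178, and the raised genes at -0.00442 in 181.

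With the BMP4 arrays left out, which removes the arrays that the labelling term needs, 2 genes changed with 181, 0 differed between 178 and 181, 1 differed between 942 and 181, 1 differed between these at 25 µM, and 8 lists passed for 942. Cenpa then stood at 0.14 in 942 with either form of the dose means. With a common mean for the doses as well, 0 genes changed with 181, 3 differed between 178 and 181, 2 between 942 and 178 and 26 between 942 and 181, and 6 lists passed for 942. With both BMP4 10 ng/ml arrays left out, Id1 (1.10), Id2 (0.76) and Id3 (1.18) passed for BMP4. Without the arrays of the highest compound dose, 0 genes changed with 181, the BMP4-lowered genes stood at -0.00333 in 942, and the raised genes at 0.00635 in 181.

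The counts of 0 genes for compounds 942 and 178, for methanol and for the dose trends of all 3 compounds were the same under every alternative run. These counts are over the mean of the doses. At 25 µM alone, 942 called 0 genes in the fit used, 1 (lower) without the labelling term and 2 (both lower) with a term for the run of title numbers. The BMP4-lowered genes in 181 passed as lower under each, with medians from -0.176 at the highest dose to -0.0414 at the lowest. All of these used the preset correlation between genes. An estimated correlation, under which no fixed list passed, was not run for the BMP4 sets.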

Other observations

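The first tests for the dose pattern below were replaced after their values had been seen, and of the tests in this part only that of the labelling method was written down beforehand. Of the 10 lists that passed along the doses of 942 and the 7 of 181, 6 were shared. The others in 942 were endothelial markers (0.13, adjusted p = 0.00493), aryl hydrocarbon receptor genes (0.12, 0.0122), unfolded protein genes (-0.071, 0.00351) and extracellular matrix genes (-0.041, 0.0246), each with adjusted p = 0.256 under an estimated correlation. The other in 181 was the inflammatory list (0.17, 2.38e-04; adjusted p = 0.168 with an estimated correlation). No test compared the slopes of a list between the compounds, so these lists do not set the compounds apart. Contractile genes had a median slope per doubling of -0.31 in 942 and -0.22 in 181 (adjusted p = 4.08e-28 and 3.46e-16; adjusted p = 0.256 and 0.398 with an estimated correlation). Hypoxia genes were lower with dose in both (adjusted p = 1.34e-07 and 2.10e-07), as were TGF-beta targets (1.09e-14 and 1.28e-05), myogenic regulators (0.00493 and 0.00189) and cholesterol genes (0.0122 and 0.0138), and the NRF2 list was higher (7.57e-04 and 1.82e-07). None of these passed with an estimated correlation, where adjusted p was 0.256 and 0.364 for hypoxia, 0.103 and 0.263 for TGF-beta, 0.417 and 0.445 for myogenic, 0.616 and 0.655 for cholesterol and 0.256 and 0.263 for NRF2 genes. Compound 178 had 0 lists past the threshold along its doses. At 25 µM Casq1 stood at -1.87 in 942 and -1.42 in 181, Egln3 at -1.67 and -1.07, Mb at -1.95 and -1.41, Nqo1 at 1.35 and 1.003, and Slc7a11 at 1.49 and 2.74, and of these values only that of Slc7a11 in 181 passed by limma.

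Genes that BMP4 lowered were lower at higher doses of 942 and 181, with median slopes of -0.0714 and -0.0721 per doubling. The genes that BMP4 raised had median slopes of -0.0199 in 942, 0.0350 in 178 and 0.0509 in 181. These raised genes thus went against the BMP4 direction in 942 and with it in 178 and 181. In all 3 compounds the title number rose with dose. An effect of that order, the same in both runs, would also reach 178, where the slope of the lowered genes was 8.65e-04. For the raised genes, 178 and 181, which lay in the same run, had slopes of like sign, so an effect of order stays open there. Random lists matched on signal had a lowest median of -0.0328 in 942 and -0.0125 in 181 (10000 lists), so genes of like signal did not move as far. In 178 the median of 8.65e-04 also lay below its lowest list (0.0061). A place outside the range therefore does not set 942 and 181 apart. The lists drew genes as if independent, and genes that move together leave such a range easily, so they are weak evidence against a bias with signal level. The 12.5 µM medians of the lowered genes in 942 and 181 lay between the others, as a response that grows with dose needs. But the smaller difference from 6.25 µM was -0.0581 between single arrays, against an SD of 0.0405 for a difference between 2 control arrays. This is weak evidence, and chance stays open. The correlations of the dose slopes across genes, which are not independent replicates, were computed first, and each lay outside its simulated range: 0.108 for 942 and 181 (simulated -0.0274 to 0.0176), -0.110 for 942 and 178 (-0.0221 to 0.0222) and 0.0555 for 178 and 181 (-0.0232 to 0.0196). The simulated noise was independent between genes, which narrows these ranges, so values outside them do not show a shared response. By steps, the 942 slope had r = 0.122 with 12.5 minus 6.25 µM of 181. With 25 minus 12.5 µM of 181 it had 0.0120, inside its range. The 181 slope had r = -0.00844 with 12.5 minus 6.25 µM of 942, inside its range, and 0.145 with 25 minus 12.5 µM.

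BMP4 10 ng/ml replicate 2 responded less than replicate 1, at 0.191 against 0.346 over the 1770 genes called at 300 ng/ml, and in it Id1 stood at 7.04 against 9.04. The highest control array reached 0.0496, so the array is unlikely to hold a control well. Measured from the untreated array of each run the ratio of the responses was 0.504, so starting from the run's own control did not close the gap. That step removes a difference in starting level only. A starting state that alters the size of the response would keep the ratio low. The bound set for excluding a different starting state was also not reached, so the test cannot decide on it. The ratio at 300 ng/ml was 0.996, but it cannot decide on weaker stimulation throughout the second run. The genes were called at 300 ng/ml, where the labelling term left replicate 2 alone to set the value. In the first run the response at 100 ng/ml (0.922) was also near that at 300 ng/ml (1.02). At 100 ng/ml replicate 1 stood at 0.889 and replicate 2 at 0.683. Measured from the untreated array of each run they stood at 0.922 and 0.692, so weaker stimulation stays open.

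The 2 arrays of BMP4 300 ng/ml, labelled by different methods, differed with an SD of 0.236 across genes. Over all probe sets the SD was 0.319. Pairs of 1 labelling method had 0.413 (untreated), 0.360 and 0.375 (BMP4 at 10 and 100 ng/ml) and 0.292 to 0.415 (methanol), so this pair showed no excess. If the labelling method had caused most of this difference, the 942 arrays would share it, but the share by covariance was -0.0284 (-0.0504, -0.0125 and -0.0222 for the single arrays). That test argues against a large share, and a small one could remain. It does not exclude a large one, because the 942 values were taken from 1 methanol array. They also hold the response to 942 and the noise of that array, which could offset a labelling part. The labelling term of the model is this same difference, so the 942 values of the model carry a difference that the 942 arrays did not share by this measure.

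When the 3 methanol arrays and the 3 arrays of a compound were split in all 10 ways into groups of 3 and fitted with limma alone, the real split called 0 genes for 942, 178 and 181, as did others, so all 10 splits had as many calls as the real one. The highest other count was 2 for 942, 0 for 178 and 0 for 181. With 10 splits a share under 0.05 is out of reach.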
